A study of Mus musculus with 12 samples.

How the data were processed

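RNA from 12 samples was hybridized to one-colour Agilent mouse gene expression arrays: kidney cells sorted for CD11b and CD11c from WT and op/op mice treated with glyoxylate, and bone marrow derived macrophages polarized to M1 or M2, 3 arrays in each of the 4 groups. Per the labels, RNA was extracted with the RNeasy Micro kit, amplified with the Ovation PicoSL WTA V2 system, labelled with Cy3 and hybridized. Per the file headers, Agilent Feature Extraction 10.7.3.1 turned the scans into spot intensity values, with the background subtracted. The deposited value table holds log2 values scaled to the 75th percentile of each array, per the labels and as tested on the files: its columns correlate at r = 1.0 with the log2 scanner signals, and their medians lie between -1.87 and -2.46. The scanner files show 3 slides. WT replicate 1 was alone on the first, the other 5 renal arrays shared the second and the 6 bone marrow arrays the third, with WT and M1 in the upper row and op/op and M2 in the lower.

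Spots of the same probe were averaged, and each array was scaled by its 75th percentile after log2 of the processed signal. A probe was kept if its signal was well above background, by the scanner software's own call, on every array of at least 1 group. That left 42966 of 55681 probes, and 24 probes with a spot marked as poor on an array were left out. Probes were named from the transcript accession in the annotation (27509), by symbol (3549) or synonym (404) in the reference, or kept the name in the file (24219). The brightest probe stood for each gene, which gave 28285 genes. Probe coordinates are those of the files (mm9). Each comparison tested the genes well above background on every array of at least 1 of its groups. The share of probes well above background, given in the report, limits which genes can be measured.

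Differences were fitted with limma 3.58.1 in R 4.3.3 on all 12 arrays in 4 groups without covariates, with p-values adjusted by Benjamini and Hochberg and called under 0.05. Renal against bone marrow was the mean of the 2 renal groups minus the mean of the 2 bone marrow groups. The 30 gene lists, written before the data were examined, were tested with camera (limma) at a preset correlation of 0.01, again with a correlation estimated from the residuals, and with fry (limma), for lists with at least 3 tested genes. The polarization score was tested by an exact permutation of the 6 renal arrays. Where a probe was not well above background on any array of a group, the fold is a lower bound, computed with every signal under the 10th percentile of the signals well above background raised to it. Such a bound holds at this floor and background correction only. Some alternatives gave smaller differences. This floor for the bounds was chosen after the data had been seen, in place of the lowest signal well above background on each array, which gave larger folds. Random blocks used statmod 1.5.0. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

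The genes named were set by a rule: the 10 highest and 10 lowest called genes of each comparison (6 for renal against bone marrow) without clone, accession or predicted names, up to 4 members of each list with the smallest p, and a fixed set of genes of macrophages, polarization and stone matrix. Some genes that the rule names are not reported here. The groups, comparisons, lists, rule and most alternatives were chosen before the data were examined.

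The procedure was tested on simulated data, with changes added to 200 genes. At 2-fold and 4-fold it recovered 41% and 83% of them in op/op against WT (9 unchanged genes called, 6.8% of calls). The shares were 32% and 87% in M1 against M2 (6 genes, 4.8%) and 71% and 98% in renal against bone marrow (14 genes, 7.7%). In the real data, far more genes were called in op/op against WT (16185). The renal arrays also varied more (median residual SD 0.366) than the bone marrow arrays (0.161). The simulated shares may therefore not carry over to op/op against WT.

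The alternatives were normexp background correction (offset 50), quantile normalization, the deposited values, no filter, a filter on all 12 arrays, a floor at the 10th percentile of well above background signals, the mean of a gene's probes, every probe on its own, only the 2 groups compared, eBayes with trend and robust, array weights, slide as a term, replicate number as a block, a 2-fold threshold, sets at least 4-fold apart, the fixed markers in place of the called genes, and leaving out each array. Cyclic loess, centring on the median of genes above background on all 12 arrays, agreement with the next brightest probe and slide as a random block were added after the data had been seen.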

Results

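Gene expression was measured on 12 one-colour Agilent mouse arrays, 3 in each of 4 groups. Wild-type (WT) and op/op mice of the same mixed background received 80 mg/kg of glyoxylate for 6 days, a treatment that forms calcium oxalate crystals in the kidney. Cells carrying the myeloid surface proteins CD11b and CD11c were then sorted magnetically from the kidney. The op mutation lies in Csf1, the gene for macrophage colony-stimulating factor (M-CSF), which macrophages need for survival and growth. Bone marrow derived macrophages (BMDM) served as reference cells: M1 cells were polarized with lipopolysaccharide and GM-CSF, M2 cells with IL-4 and M-CSF. The share of probes well above background was lowest on the op/op renal arrays (63.1% to 68.8%) and the M2 arrays (64.8% to 65.4%), and higher on the WT renal and M1 arrays (72.9% to 79.5%). The number of arrays limits the precision. The labels do not say that replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. The fit pools the spread of all 4 groups, and renal arrays varied more than bone marrow arrays (median residual SD 0.366 against 0.161). SEs and p-values of the fit therefore tend to be too small for op/op against WT and too large for M1 against M2.

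The first 3 principal components held 71.7%, 9.9% and 8.9% of the variance. Component 1 separated kidney from bone marrow cells and component 2 separated M1 from M2. Pairs of arrays correlated at r = 0.945 to 0.973 within WT renal, 0.972 to 0.98 within op/op renal, 0.99 to 0.991 within M1 and 0.985 to 0.99 within M2, across genes. WT and op/op arrays correlated at 0.859 to 0.965, and WT replicate 4 lay nearer to the op/op arrays on component 1 than the other WT arrays did. The median residual SD was 0.366 on the log2 scale among renal arrays and 0.161 among bone marrow arrays.

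**Figure D1:**
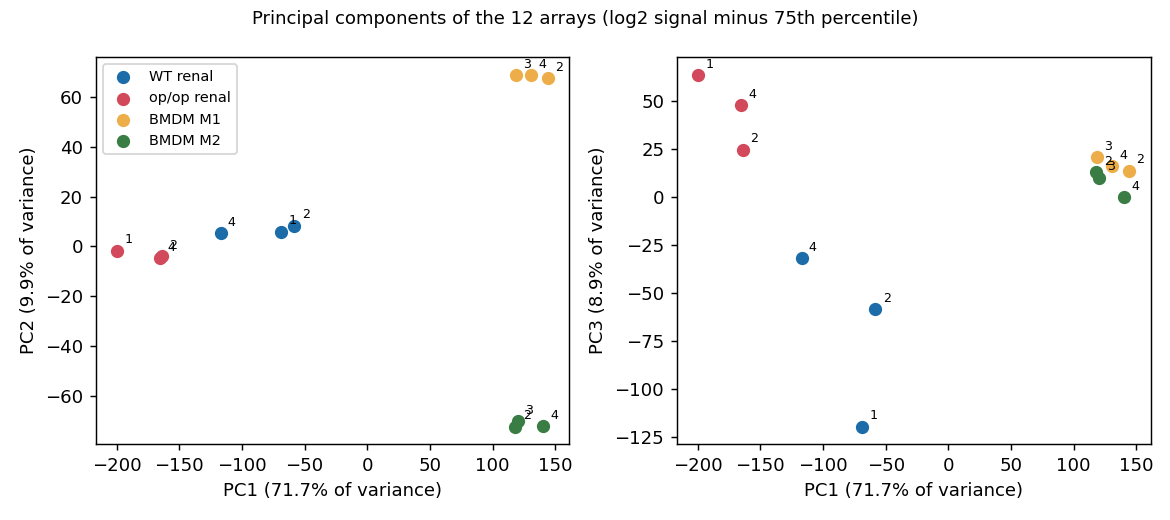
Principal components 1 to 3 of the 12 arrays, from log2 signal minus each array's 75th percentile; each point is an array, coloured by group and labelled with its replicate number. Kidney and bone marrow cells part along component 1 (71.7% of variance), M1 and M2 along component 2 (9.9%).

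The comparison of op/op with WT renal cells asks what differs between kidney myeloid cells of stone-model mice with and without M-CSF. Csf1 itself was at -0.12 ± 0.10 in WT, -0.50 ± 0.45 in op/op, 3.28 ± 0.15 in M1 and 3.23 ± 0.10 in M2 cells (log2 signal relative to the array's 75th percentile, mean ± SD, n = 3 each; probe at chromosome 3, 107544333 to 107544392, mm9). It did not differ between op/op and WT (-0.39 ± 0.21, SE, limma adjusted p = 0.129), but passed without op/op replicate 2 (-0.62). The op mutation leaves the transcript in place, so this level checks nothing about the genotype. All differences below are op/op minus WT on the log2 scale with the SE of the limma fit, n = 3 arrays per group.

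Macrophage genes were lower in op/op than in WT cells. Of the 19 tested genes of the macrophage identity list, 16 fell and 0 rose (16 and 0 adjusted over the list alone). The median of all 27092 tested genes was 0.19, and list medians are given relative to it: -1.76 for this list (adjusted p = 1.23e-05 in the list test, adjusted p = 0.329 with an estimated correlation). Cx3cr1, the fractalkine receptor, fell 5.96-fold (-2.58 ± 0.33), and C1qc, a chain of complement C1q made by tissue macrophages, fell 4.46-fold (-2.16 ± 0.29). Adgre1, which encodes F4/80, fell 4.27-fold (-2.09 ± 0.35), and Itgax, which encodes the sorting antigen CD11c, fell 3-fold (-1.58 ± 0.19). Itgam, which encodes the sorting antigen CD11b, did not pass on its brightest probe (0.34 ± 0.21, adjusted p = 0.174), and 2 dimmer probes gave -0.46 and -0.72. It passed without WT replicate 1 (0.58). Csf1r, the M-CSF receptor, stood at 0.11 ± 0.15 (adjusted p = 0.505) on its brightest probe, while its 2 other probes gave -1.48 and -1.77.

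Receptors and organelles of phagocytes fell with them. Among phagocytic and scavenger receptors 11 of 16 genes fell and 0 rose (11 and 0 adjusted over the list alone, median -1.39, adjusted p = 0.343 with an estimated correlation). They included Axl, a receptor for apoptotic cells (-1.76 ± 0.25), Clec7a, the beta-glucan receptor dectin-1 (-1.68 ± 0.24), and the Fc receptor gene Fcgr2b (-2.05 ± 0.38). In the lysosome list 16 of 20 genes fell and 1 rose (16 and 2 adjusted over the list alone, median -1.40, adjusted p = 0.329 with an estimated correlation), among them Lamp2 (-1.73 ± 0.24) and the protease gene Ctsb (-1.79 ± 0.27). In MHC class II presentation 7 of 11 genes fell and 0 rose (7 and 0 adjusted over the list alone, median -1.65, adjusted p = 0.329 with an estimated correlation): H2-Aa fell 4.95-fold (-2.31 ± 0.29), H2-Eb1 3.12-fold (-1.64 ± 0.20), and Ctss, which processes the invariant chain, had -1.90 ± 0.27. The H2 genes lie in the MHC, where different haplotypes of the animals stay undecided, as given below, and may bear on their values. Of the complement list 7 of 11 fell and 0 rose (7 and 0 adjusted over the list alone, median -1.29, adjusted p = 0.329 with an estimated correlation), with Cfb at -1.99 ± 0.37.

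Inflammatory and alternative-activation markers both fell in op/op. Of the M1 markers 16 of 26 fell and 2 rose (17 and 2 adjusted over the list alone, median -1.26), and of the M2 markers 16 of 25 fell and 2 rose (16 and 2 adjusted over the list alone, median -1.24); for both, adjusted p = 0.329 with an estimated correlation. Il6 fell at least 4.07-fold and Arg1, which encodes arginase 1, at least 1.86-fold. Neither was well above background on any op/op array, so each fold is a bound, taken after every signal under a common floor, the 10th percentile of the signals well above background, was raised to it. The bounds hold at this floor only: over the alternatives the smallest falls were -1.03 for Il6 and -0.39 for Arg1. Tnf fell 3.94-fold (-1.98 ± 0.44), Il1b 2.28-fold (-1.19 ± 0.21) and Mrc1, the mannose receptor, 4.01-fold (-2.00 ± 0.39). Il4ra, the IL-4 receptor alpha chain, rose on its brightest probe (0.86 ± 0.15) and stood at -0.03 on another. Il12b (-0.98 ± 0.29, well above background on 1 of 3 op/op arrays) lost its call with normexp background correction (0.06), with the floor (-0.01), with only the 2 groups in the fit, and without WT replicate 2 (-0.64) or op/op replicate 1 (-0.78). Arg1 lost its call with normexp (-0.39), and Chil3 gained one without op/op replicate 4 (0.57). Nos2 (-0.01 ± 0.28, adjusted p = 0.979), Chil3 (0.34 ± 0.23, adjusted p = 0.211) and Il10 (0.34 ± 0.38, adjusted p = 0.452) did not pass, and Retnla and Cd163 were not tested because neither group had them well above background on all arrays.

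Chemokine, interferon and NF-kB genes followed the same direction. Of the chemokines 16 of 21 fell and 2 rose (17 and 2 adjusted over the list alone, median -1.94), led by Ccl7, a monocyte attractant, which fell 12.2-fold (-3.61 ± 0.50), and Cxcl10 (-3.10 ± 0.36, well above background on 2 of 3 op/op arrays). Of the interferon-stimulated genes 18 of 23 fell and 1 rose (19 and 1 adjusted over the list alone, median -1.26), such as Oas2 (-1.88 ± 0.25) and Mx1 (-1.63 ± 0.27). Of the inflammasome and NF-kB list 9 of 13 fell and 1 rose (10 and 1 adjusted over the list alone, median -1.14), including Tnfaip3, an NF-kB inhibitor (-2.12 ± 0.31). For all 3 lists adjusted p = 0.329 with an estimated correlation.

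Genes tied to stones and matrix were mixed. In the tubular injury and crystal-binding list 5 of 13 fell and 1 rose (5 and 1 adjusted over the list alone, median -0.70, list test adjusted p = 0.0822). The list passed with normexp, without a filter, with the mean of all probes, with only the 2 groups in the fit, with array weights and without WT replicate 4 (median -0.62, not relative to all genes). Fn1, fibronectin, fell 4.81-fold (-2.27 ± 0.31), Vcam1 fell 6.47-fold (-2.69 ± 0.52), and Spp1, osteopontin, a protein of stone matrix, fell 3.25-fold (-1.70 ± 0.51). The Spp1 call ended without WT replicate 2 (-1.09) and without op/op replicate 1 (-1.25). Cd44, an osteopontin and hyaluronan receptor, was at 0.16 ± 0.16 (adjusted p = 0.365) on its brightest probe, with -0.91 to -1.26 on 3 other probes. Of the matrix metalloproteinases and inhibitors 3 of 9 fell and 1 rose (3 and 1 adjusted over the list alone, median -0.55, list test adjusted p = 0.0864). Mmp13, a collagenase, had -2.96 ± 0.51 (well above background on 1 of 3 op/op arrays). Timp1, a protease inhibitor, had 1.75 ± 0.66, a call that ended without WT replicate 1 (0.74) or 2 (1.92) and without op/op replicate 1 (1.64), 2 (1.78) or 4 (1.84). Of the CSF receptors and ligands 2 of 7 fell and 0 rose (2 and 0 adjusted over the list alone, median -0.31, list test adjusted p = 0.50), one of them Il34, the other CSF-1 receptor ligand (-1.32 ± 0.30).

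Of the proximal tubule markers 12 of 14 fell and 0 rose (12 and 0 adjusted over the list alone, median -1.78, adjusted p = 0.329 with an estimated correlation), such as the phosphate transporter gene Slc34a1 (-1.97 ± 0.32, 3.93-fold) and the fatty acid transporter gene Slc27a2 (-2.76 ± 0.35). In the distal nephron and collecting duct list 4 of 12 rose and 1 fell (4 and 1 adjusted over the list alone, list test adjusted p = 0.707). Its median of -0.09 and its mean of 0.03, neither relative to all genes, differ in sign. The water channel genes Aqp2 (1.08 ± 0.21) and Aqp3 (1.27 ± 0.26) and the sodium channel gene Scnn1g (1.79 ± 0.41) rose. For scale, 221 olfactory receptor probes well above background on all 12 arrays had a median op/op minus WT of 0.89. Endothelial (1 of 12 rose, 0 fell, median 0.10, list test adjusted p = 0.284), podocyte (1 of 5 rose, 1 fell, median -0.79, adjusted p = 0.573) and fibroblast and mural cell markers (0 of 9 rose, 3 fell, median -0.57, adjusted p = 0.173) did not pass as lists, with the same counts adjusted over the list alone. Endothelial markers passed with array weights and without op/op replicate 1 (medians, not relative to all genes, of 0.76 and 0.53). All 3 tested Y-linked genes of the sex-linked list fell (3 adjusted over the list alone, median -2.15, adjusted p = 0.329 with an estimated correlation): Eif2s3y (-1.96 ± 0.28), Ddx3y (-1.37 ± 0.26) and Kdm5d, whose call ended with normexp (-0.33) and with the floor (-0.21). The call of this list ended without WT replicate 1 and with the floor, where its medians, not relative to all genes, were -1.45 and -1.37. The sex of the animals is not given in the sources used here, so a different sex make-up of the groups is not excluded for any op/op against WT value.

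Some lymphocyte and granulocyte genes rose, but none of these lists passed the list test. Over all tested genes 8708 of 27092 were called higher. T cell markers had 5 of 11 higher and 1 lower (median 0.42, adjusted p = 0.196), B cell markers 4 of 10 higher and 2 lower (median 0.66, adjusted p = 0.223) and NK cell markers 4 of 7 higher and 0 lower (median 0.65, adjusted p = 0.247). Neutrophil markers had 4 of 13 higher and 1 lower (median 0.12, adjusted p = 0.432), dendritic cell markers 1 of 12 higher and 4 lower (median -0.27, adjusted p = 0.436). These counts were the same adjusted over the list alone. Single genes that rose included Cd3e of the T cell receptor complex (1.43 ± 0.20), Ms4a1, which encodes CD20 of B cells (1.80 ± 0.31), Prf1, perforin (0.84 ± 0.17), and the neutrophil granule gene Ngp (1.77 ± 0.34). The olfactory receptor probes named above had a median of 0.89, near the value of Prf1, so a rise of that size is not particular to lymphocyte genes. Of the monocyte markers 5 of 9 fell and 1 rose (5 and 1 adjusted over the list alone, median -1.09, list test adjusted p = 0.0293, adjusted p = 0.329 with an estimated correlation), with the chemokine receptor gene Ccr2 at -1.50 ± 0.23. The call of this list ended with cyclic loess and without op/op replicate 4 (medians, not relative to all genes, of -0.73 and -0.79).

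**Figure D2:**
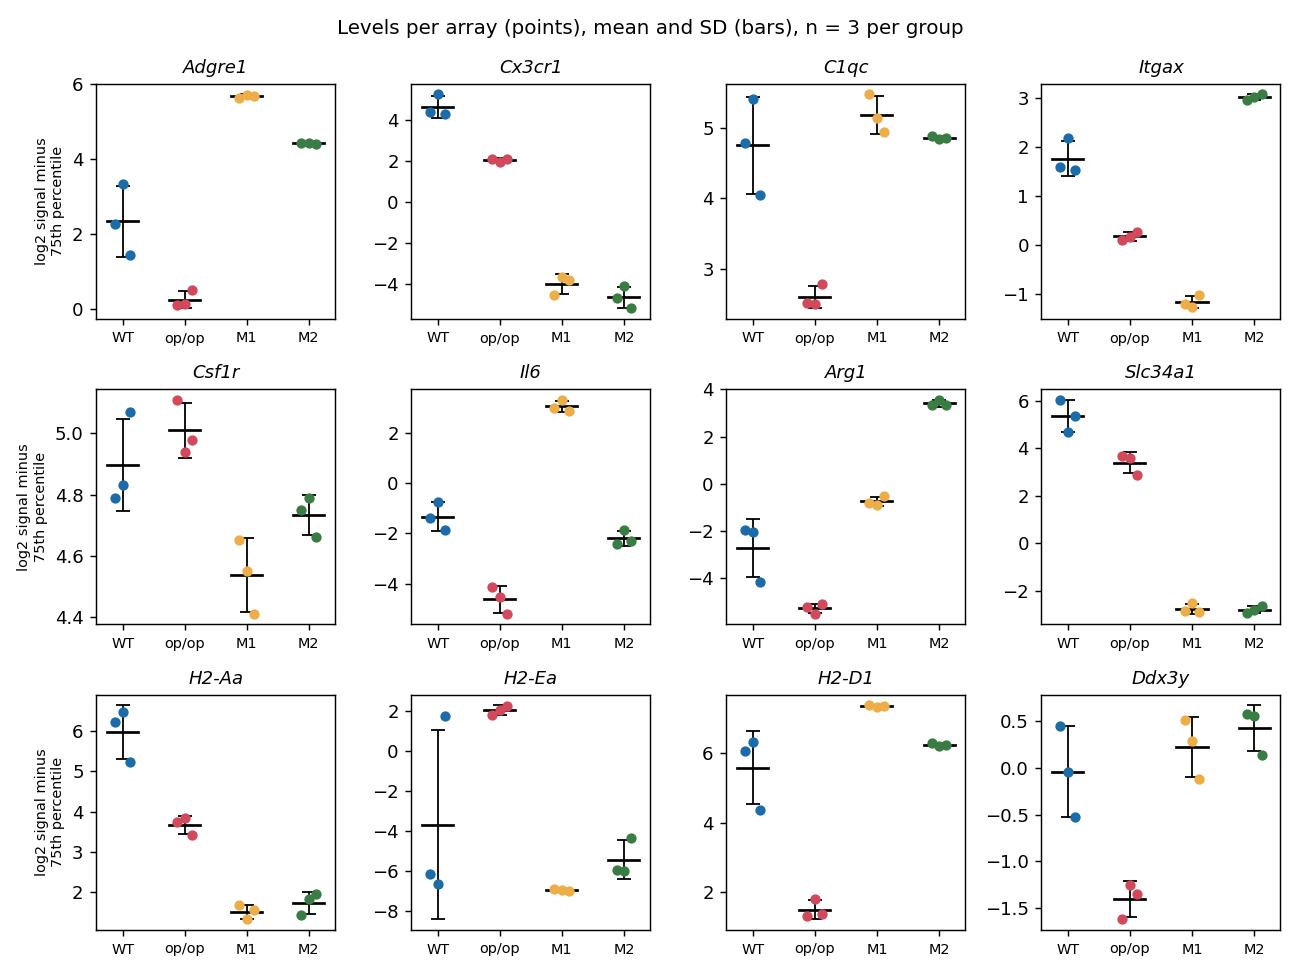
Levels of 12 genes on each array (log2 signal minus the array's 75th percentile); points are arrays, horizontal lines the mean and bars the SD of 3 arrays per group. Cx3cr1, C1qc and Adgre1 are lower on every op/op array than on every WT array, and H2-Ea is high on the 3 op/op arrays and on WT replicate 4.

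Some large differences were in genes of the major histocompatibility complex on chromosome 17. H2-Ea, an MHC class II alpha chain gene that some mouse haplotypes do not express (probe at chromosome 17, 34481469 to 34481528, mm9), was higher in op/op (5.73 ± 1.65, adjusted p = 0.0124, range over the alternatives 1.34e-05 to 0.0555). WT replicates 1 and 2 were not well above background, so the size of this difference is uncertain, and with the floor it was 3.71. It was at 2.06 ± 0.24 (SD) in op/op, at 1.77 on WT replicate 4, and at -6.14 and -6.66 on WT replicates 1 and 2; its call ended without WT replicate 1 (4.51) or 2 (4.24). The class I genes H2-D1 (-4.09 ± 0.39, 17-fold lower) and H2-Q5 (-4.68 ± 0.38, 25.6-fold lower) were among the lowest. Other genes that fell included Pf4, platelet factor 4 (at least 19.5-fold), Pctp (at least 4.55-fold), the sulfate transporter gene Slc13a1 (at least 6.28-fold), Slc6a20b (at least 6.98-fold), Wfdc17 (-3.41 ± 0.34) and the interferon-inducible gene Ifi202b (-3.37 ± 0.33). The bounds hold at the floor used only. Over the alternatives the smallest falls were -2.94 for Pf4, -1.38 for Pctp, -1.49 for Slc13a1 and -1.48 for Slc6a20b, smaller than these bounds. Genes that rose from WT signals not well above background on any array included Frzb, a secreted Wnt antagonist (at least 4.49-fold), Myh3 (at least 3.14-fold), Lcn9 (at least 1.93-fold), the cytokine gene Il7 (at least 3.33-fold) and Cd96 (at least 2.43-fold).

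Over all genes, limma called 16185 of 27092 (8708 higher and 7477 lower in op/op), of which 7190 differed at least 2-fold. Fewer genes were called with only the 2 renal groups in the fit, as given below. Which direction holds more genes depends on the processing, with 10482 higher and 6359 lower with normexp, 7911 and 8248 with quantile normalization, and 5810 and 6076 without op/op replicate 1. Of the 30 lists 17 passed the list test (camera with a preset correlation), all lower in op/op, and 0 passed with an estimated correlation. Fry asks whether a list's own genes move on balance in one direction, its mixed form whether they move in either direction, and neither compares the list with other genes. It called 25 lists, among them T cell, B cell and NK cell markers as higher in op/op (fry adjusted p = 0.0235, 0.0125 and 0.0271). WT replicate 1 was hybridized alone on its slide; with slide as a term, which leaves the comparison within the slide that held the other 5 renal arrays, 14257 genes were called. List medians there, not relative to all genes, were -1.59 for macrophage identity (-1.58 without the term), -1.34 for proximal tubule markers (-1.59), -1.13 for M1 markers (-1.08), -1.01 for M2 markers (-1.06) and -1.56 for chemokines (-1.75). Cx3cr1 stood at -2.71, Adgre1 at -2.14 and H2-D1 at -3.86 with slide as a term. H2-Ea (4.51) lost its call there.

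M1 and M2 bone marrow macrophages were compared as references for polarization. M1 cells had far higher inflammatory genes: Cxcl10, an interferon-induced chemokine, was at least 237-fold higher, Il1b 264-fold (8.04 ± 0.21), Il6 38.1-fold (5.25 ± 0.32) and Tnf 30.8-fold (4.94 ± 0.44). M2 cells had higher alternative-activation genes: Retnla, an IL-4 induced secreted protein, was at least 559-fold higher, Mrc1 86.4-fold (-6.43 ± 0.39, M1 minus M2) and Arg1 17.8-fold (-4.15 ± 0.45). Chil3 (-2.98 ± 0.23) was also higher in M2, while Nos2 (2.10 ± 0.28) and Il10 (4.29 ± 0.38) were higher in M1 (SE, n = 3 per group). Over the alternatives the smallest differences were 7.26 for Cxcl10 and -8.29 for Retnla, so their bounds hold at the floor used only.

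By list, 24 of 28 M1 markers rose in M1 and 0 fell (25 and 0 adjusted over the list alone), with a median of 4.26 relative to all genes, whose own median was -0.01. Of the interferon-stimulated genes 22 of 23 rose and 0 fell (22 and 0 adjusted over the list alone, median 5.24), such as Ifit3 (8.40 ± 0.28) and Gbp3 (6.66 ± 0.22). Chemokines had 17 of 21 higher and 1 lower (18 and 1 adjusted over the list alone, median 3.45), with Ccl5 at 7.22 ± 0.21. Proliferation genes had 22 of 24 lower in M1 and 0 higher (22 and 0 adjusted over the list alone, median -1.43), such as the cyclin gene Ccna2 (-2.36 ± 0.16) and Mcm5 (-1.94 ± 0.19). These 4 lists held with an estimated correlation (adjusted p = 0.024, 0.024, 0.0415 and 0.0415). The inflammasome and NF-kB list had 11 of 13 higher and 1 lower (11 and 1 adjusted over the list alone, median 2.11, adjusted p = 0.0569 with an estimated correlation), for example Nlrp3 (2.89 ± 0.21). Among M2 markers 15 of 27 fell in M1 and 4 rose (17 and 5 adjusted over the list alone, median -1.21, adjusted p = 0.215 with an estimated correlation), Pparg (-3.67 ± 0.24) and Klf4 (-2.48 ± 0.19) among those that fell.

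Smaller list shifts were also called. Complement (4 of 11 higher, 0 lower, adjusted p = 0.224 with an estimated correlation; median 0.73) rose in M1, with Cfb at 8.39 ± 0.37. Glycolysis (5 of 16 higher, 0 lower, 7 and 1 adjusted over the list alone, median 0.58, adjusted p = 0.542 with an estimated correlation) rose with Slc2a1, the glucose transporter GLUT1 (1.88 ± 0.23), and Pfkfb3 (2.63 ± 0.25). Fatty acid oxidation (5 of 13 lower, 0 higher, 6 and 0 adjusted over the list alone, median -0.53, adjusted p = 0.65 with an estimated correlation) fell, and lysosome genes (7 of 22 lower, 1 higher, 9 and 2 adjusted over the list alone, median -0.47, adjusted p = 0.676 with an estimated correlation) fell with Atp6v0d2 (-4.03 ± 0.35). Fibroblast and mural cell markers rose (5 of 11 higher, 0 lower, 6 and 0 adjusted over the list alone, median 0.64, adjusted p = 0.274 with an estimated correlation) and neutrophil markers fell (5 of 15 lower, 1 higher, 7 and 1 adjusted over the list alone, median -0.78, adjusted p = 0.507 with an estimated correlation), with a median, not relative to all genes, of -0.51 without M2 replicate 4. The call of the neutrophil list ended with only genes well above background on all 12 arrays. Itgax was lower in M1 (-4.17 ± 0.19) and Aif1 higher (2.80 ± 0.18), and the macrophage identity list as a whole did not pass (median 0.29, adjusted p = 0.298). MHC class II, phagocytic, erythroid and sex-linked lists had medians, means or tests of different sign and did not pass. In all, limma called 4716 of 26204 genes (2266 higher and 2450 lower in M1), 2818 of them at least 2-fold apart. The balance of directions depends on the processing here too (2461 and 2276 with cyclic loess), and so does the number called, which reached 10416 with array weights. Of the 30 lists 12 passed and 14 passed fry. All 6 arrays lay on one slide, M1 in its upper and M2 in its lower row.

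The next question is on which side of the M1 to M2 axis the op/op renal cells lie from WT. The score of each array was the mean level of the 1602 genes at least 2-fold higher in M1 minus that of the 1216 genes at least 2-fold higher in M2. It was 2.12 ± 0.02 in M1 and -1.75 ± 0.04 in M2 cells (mean ± SD, n = 3). WT renal cells had 0.09 ± 0.06 and op/op renal cells -0.04 ± 0.02, a difference of -0.125 seen on 3 of 3 op/op arrays (exact permutation p = 0.1 over 20 arrangements, the smallest p this design allows). Both parts of the score were lower on 3 of 3 op/op arrays than on any WT array, with differences of -0.419 for the M1 genes and -0.294 for the M2 genes. Over the alternatives the difference of the score ranged from -0.357 to -0.042. A single reference array moves it: it was -0.042 without M1 replicate 2 (exact permutation p = 0.5) and -0.241 without M2 replicate 4. Tested as sets in op/op against WT, the M1 genes fell (647 of 1378 tested fell, 155 rose, list test adjusted p = 4.27e-09). The M2 genes fell too (514 of 1139 fell, 179 rose, list test adjusted p = 4.78e-07). Medians of the 2 sets, not relative to all genes, were -0.55 and -0.52. Both sets held with an estimated correlation (adjusted p = 0.0314). Across 25011 genes tested in both comparisons, op/op minus WT and M1 minus M2 correlated at Pearson r = -0.038 (Spearman rho 0.062; genes are not independent replicates). The Pearson value ranged from -0.125 to 0.004 over the alternatives.

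**Figure D3:**
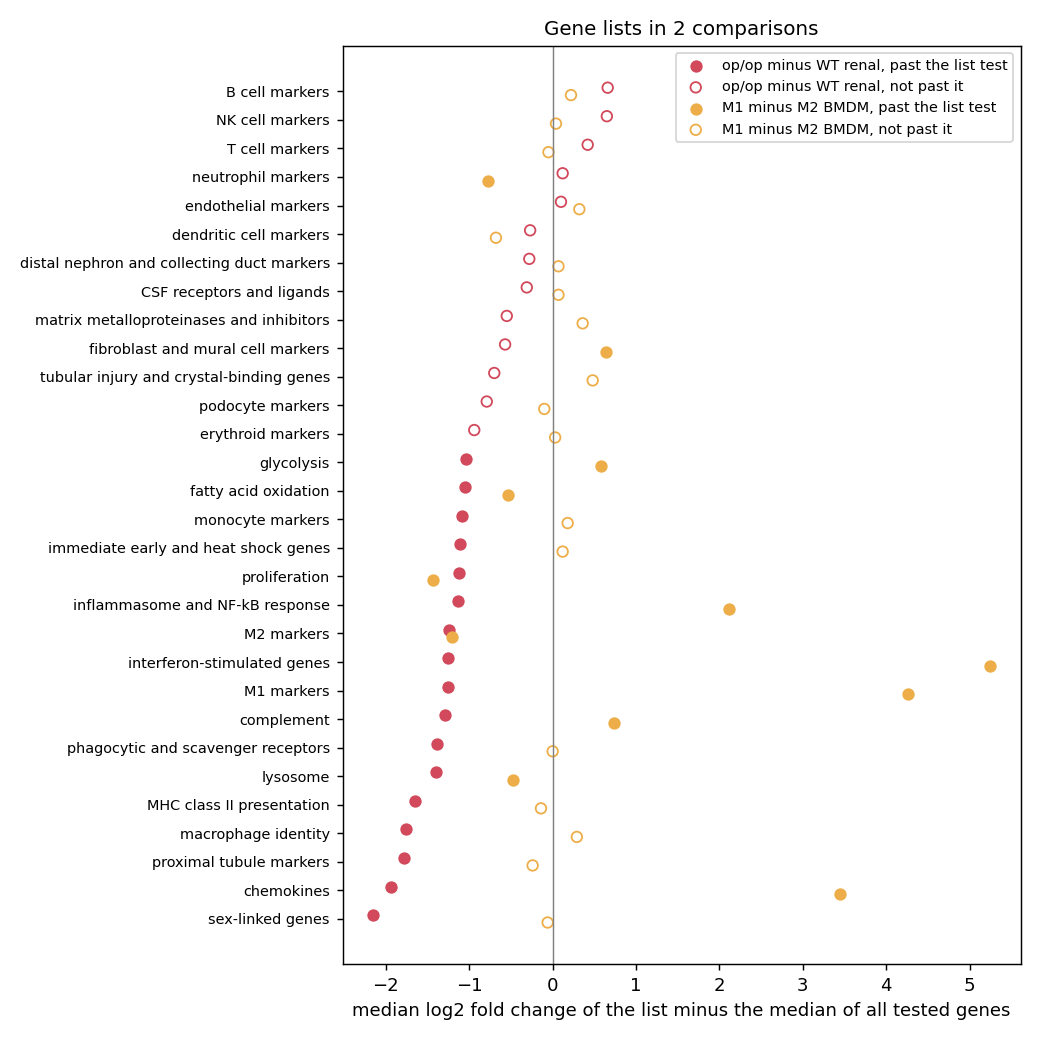
Median log2 difference of each of the 30 gene lists minus the median of all tested genes, for op/op minus WT renal cells and M1 minus M2 cells; filled points passed the list test with a preset correlation, open points did not. M1 and M2 marker lists lie on opposite sides in bone marrow cells (4.26 and -1.21) and on the same side in op/op against WT (-1.26 and -1.24).

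Renal cells of both genotypes were set against both bone marrow groups to describe the sorted fraction. Kidney genes were far higher in the sorted cells: Umod, uromodulin of the thick ascending limb, was at least 325-fold higher, Slc34a1 144-fold (7.17 ± 0.22), and the endothelial gene Tie1 was at least 18.1-fold higher (SE, n = 6 per tissue). H2-Eb1 was 31.0-fold higher in renal cells (4.95 ± 0.14), and Adgre1 was 13.5-fold lower (-3.75 ± 0.25). For genes well above background on only some arrays the difference is given with the floor. It was 6.70 for Cx3cr1 (on 2 of 6 bone marrow arrays), -4.24 for Arg1 (on 3 of 6 renal arrays) and -8.37 for Gpnmb, a glycoprotein of lysosomes (on 1 of 6 renal arrays).

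All tested distal nephron (12 of 12), endothelial (12 of 12), podocyte (5 of 5) and erythroid (4 of 4) markers rose, and 13 of 14 proximal tubule markers did, with 0 lower in these lists. Their medians relative to all genes, whose own median was 0.37, were 2.98, 3.92, 3.69, 3.89 and 3.31 (adjusted p = 0.324 for distal nephron and 0.322 for the 4 others with an estimated correlation). MHC class II presentation (10 of 11 higher, 1 lower, median 2.36), dendritic cell markers (9 of 12 higher, 1 lower, median 1.44) and B cell markers (9 of 10 higher, 0 lower, median 1.08) also rose (adjusted p = 0.322 each with an estimated correlation), as did immediate early and heat shock genes (11 of 12 higher, 0 lower, median 2.36, adjusted p = 0.368 with an estimated correlation), such as Fosb (4.30 ± 0.19), Hspa1a (5.68 ± 0.30) and the dendritic cell gene Cd209a (at least 9.58-fold). These counts were the same adjusted over the list alone.

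Lysosome (20 of 22 lower, 0 higher, median -2.73), glycolysis (15 of 16 lower, 0 higher, median -2.61), interferon-stimulated (22 of 23 lower, 1 higher, median -2.40) and phagocytic genes (15 of 19 lower, 0 higher, median -1.87) fell in renal cells, as did fibroblast and mural cell markers (10 of 11 lower, 1 higher, median -4.00); for all 5, adjusted p = 0.322 with an estimated correlation. Examples were the cathepsin gene Ctsb (-2.83 ± 0.19), Pkm (-3.07 ± 0.20), Gbp2 (-2.62 ± 0.15), Cd36 (-5.29 ± 0.31) and Col1a1 (-5.84 ± 0.20). Macrophage identity (14 of 19 lower, 3 higher, median -1.64, adjusted p = 0.37 with an estimated correlation) and matrix metalloproteinases and inhibitors (11 of 12 lower, 1 higher, median -2.27, adjusted p = 0.123 with an estimated correlation) fell too. The counts of these 7 lists were the same adjusted over the list alone. The other lists that fell were M2 markers, neutrophil markers and proliferation (adjusted p = 0.368 with an estimated correlation) and chemokines, complement and fatty acid oxidation (adjusted p = 0.37 with an estimated correlation). The complement call ended with quantile normalization, the filter on all 12 arrays, the floor, array weights, the replicate block and cyclic loess, and without op/op replicate 2 (median -1.17, not relative to all genes) or M1 replicate 2 (-1.18). The filter on all 12 arrays also ended the calls of chemokines and of M2, neutrophil, dendritic cell and B cell markers, quantile normalization and cyclic loess that of chemokines, and the replicate block that of neutrophil markers. Limma called 23293 of 28285 genes (13768 higher and 9525 lower in renal cells); 22 of 30 lists passed, 0 of them with an estimated correlation. The bone marrow arrays lay on a slide of their own, so slide and tissue cannot be told apart, and with slide as a random block 17825 genes were called.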

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

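Cyclic loess, centring on the median gene, the next brightest probe and the random slide block were chosen after the data had been seen. Of the 30 lists, 16 to 19 passed in op/op against WT over the alternatives, 11 to 13 in M1 against M2 and 16 to 24 in renal against bone marrow. A change of direction was counted as a reversal only where the value passed in the main fit or in the alternative. By this rule no list reversed. Of 3030 values of named genes in op/op against WT 2924 kept their side of the threshold and, where called, their direction. So did 2596 of 2739 in M1 against M2 and 3406 of 3433 in renal against bone marrow. Values called in neither setting may have changed direction. The polarization score of op/op against WT lay between -0.357 and -0.042 (exact permutation p from 0.1 to 0.5).

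With a threshold of at least 2-fold, 7190, 2818 and 15467 genes were called in op/op against WT, M1 against M2 and renal against bone marrow, fewer by construction. Called alike on the next brightest probe were 2704, 815 and 4890, among genes with at least 2 passing probes. With only the 2 groups in the fit, 10346 genes were called in op/op against WT and 9732 in M1 against M2, and with array weights 10416 in M1 against M2. The bone marrow arrays vary less (median residual SD 0.161) than the renal ones (0.366), and the fit of 4 groups pools them. Without a filter on dim probes the correlation of op/op minus WT with M1 minus M2 was -0.125.

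Some single genes reversed, and the cause was not tested. With normexp, Csf1r gave -1.56 and Il12b 0.06 in op/op against WT, and Csf1r -1.47 and Csf2 0.2 in renal against bone marrow. With the mean of all probes, op/op against WT gave -1.04 for Csf1r, -0.78 for Cd44, -0.63 for Csf2rb and -0.3 for Vcan, and renal against bone marrow -1.02 for Csf1r and -0.46 for Itgam. In that comparison Il12b gave -0.85 with quantile normalization and -0.7 with cyclic loess.

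Leaving out 1 array gave 11886 to 17614 genes in op/op against WT and 3321 to 3515 in M1 against M2. With replicate number as a block the counts were 14570, 3674 and 17915, but the numbers do not pair the arrays: residuals of arrays with the same number correlated at -0.164, 0.071 and -0.063 in renal and -0.072, 0.144 and 0.084 in bone marrow cells. With slide as a random block 15541 genes were called in op/op against WT. Slide as a fixed term was not run for renal against bone marrow, where no slide holds both tissues, and a fit of the arrays as 2 groups was run there only for the splits of the arrays. Signal over background limits the folds of dim genes, which are bounds, at the chosen floor only, where a group has no array well above it.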

Other observations

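Proliferation and metabolic genes were lower in op/op than in WT cells, a part of the comparison not described above. Of the proliferation list 17 of 24 genes fell and 3 rose (18 and 3 adjusted over the list alone, median -1.12 relative to all genes), such as Pcna, the DNA polymerase clamp (-1.63 ± 0.19, SE, n = 3 per group), and Mcm6 of the replicative helicase (-1.32 ± 0.18). Of the glycolysis list 13 of 16 fell and 1 rose (14 and 1 adjusted over the list alone, median -1.04), with the hexokinase gene Hk2 at -2.30 ± 0.32 and Ldha at -0.97 ± 0.14. Fatty acid oxidation had 9 of 13 lower and 0 higher (10 and 0 adjusted over the list alone, median -1.05), with Cpt2 at -1.36 ± 0.20. Immediate early and heat shock genes had 10 of 12 lower and 0 higher (11 and 0 adjusted over the list alone, median -1.11), with Btg2 at -1.04 ± 0.23 and Dusp1 at -1.01 ± 0.23. For these 4 lists adjusted p = 0.329 with an estimated correlation. Erythroid markers did not pass (2 of 4 lower, 0 higher, the same adjusted over the list alone, median -0.94, list test adjusted p = 0.197).

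The tests chosen only after the result was seen were the splits within kidney and within bone marrow, kidney cells in place of macrophages, array position for the macrophage list and for H2-Ea, antigen-presenting cells, and the haplotype of WT replicate 4. The limits of the MHC window (33.5 to 37.5 Mb of chromosome 17) and the reading of a tie in its test were also set after values were seen.

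The first pattern is the fall of macrophage genes in op/op. List medians in this paragraph are not relative to all genes. Compression of the signals on the op/op arrays, with bright genes lower and dim genes higher, is argued against: the list median of -1.58 lay at percentile 0 of 10000 lists matched on level, 95% of which lay between -0.70 and 0.63. Fewer macrophages with a mix of kidney cells of unchanged make-up in their place would raise all kidney markers alike. The medians moved apart (proximal tubule -1.59, distal nephron -0.09, endothelial 0.29), which argues against such a mix only. Replacement by 1 kidney cell type or by lymphocytes is not covered by this test. T, B and NK cell lists had medians of 0.61, 0.85 and 0.84, and none passed the list test. More distal nephron cells stay open, but 4 of 12 such markers rose, a share near that of all tested genes (8708 of 27092). Array position cannot be told apart from genotype here: the list median of M2 minus M1, the lower against the upper row, was -0.28, but its 18 genes go both ways (SD 1.81) and row follows polarization there. What may remain is array position, the op genotype acting on the cells or on which cells were sorted, none of which was tested apart, and amplification, while slide as the whole cause is argued against by the median of -1.59 with slide as a term, where 14257 genes were called.

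The second pattern is the 8708 genes called higher in op/op. Array position on the renal slide cannot be told apart from genotype for these genes. A row effect shared with the bone marrow slide is argued against by 221 olfactory receptor probes, though row follows polarization there. Over these probes, op/op minus WT (median 0.89) correlated with M2 minus M1 (median -0.01) at r = -0.185. Dim signals are not covered by this test. The SD of the negative controls was 4.75 to 6.04 on lower-row arrays and 3.30 to 4.19 on upper-row arrays, so a shared row effect on dim signals stays open. Signal of single probes and not of transcripts may account for part of it, since the next brightest probe was called in the same direction 18 percentage points less often for genes called higher (44%) than for genes called lower (62%). Of the former 11.3% had a next probe called the opposite way, against 5.9% of the latter. The next probes of higher genes are also dimmer, so a lower power on them stays open for the smaller share called in the same direction. Lower power does not by itself give calls the opposite way. In M1 against M2 the opposite calls were 0.3% for both directions, and in renal against bone marrow 12.7% and 10.8%.

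The third pattern is H2-Ea higher and H2-D1 and H2-Q5 lower in op/op. A lower share of antigen-presenting cells is argued against as the source of the rise of H2-Ea, since the median of H2-Aa, H2-Ab1 and H2-Eb1 was -1.64. H2-Aa, H2-Ab1 and H2-Eb1 lie in the MHC too, so haplotypes may also bear on their median. Whether the share of antigen-presenting cells was lower is not decided by it. A lower share stays open as a source of the fall of H2-D1 and H2-Q5. Array position cannot be told apart from genotype for the 3 genes together. H2-Ea does not follow row: 1 upper-row array, WT replicate 4, has it well above background, and 0 of 6 bone marrow arrays do. Within the renal slide this rests on 1 array. H2-Q5 is also lower in the lower row of the bone marrow slide (M1 minus M2 4.77, and 1.10 for H2-D1, which did not pass). Different MHC haplotypes in the mixed background are a candidate explanation left undecided: 9 of 220 genes of the window (4.1%, against 1.8% of all) differed over 4-fold, which equals the upper limit set from other windows, with 95.5% of them below. A copy of the op/op haplotype in WT replicate 4 is undecided too (median way towards op/op 0.42, against 0.27 for other genes, percentile 93.6). A separate test concerned other large differences between op/op and WT and does not bear on these MHC genes. The segment within 10 Mb of Csf1 held 3 of 208 genes over 4-fold apart, percentile 33.3. That argues against linkage to Csf1 as the source of those other differences.

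Other splits of the arrays were counted. Of the 10 splits of the 6 renal arrays, 1, the real one, called as many as 16185 genes, and the highest other called 0 with limma (6370 at an unadjusted p under 0.05). Of the 10 splits of the 6 bone marrow arrays, 1, the real one, called as many as 4716, and the highest other 0 with limma (453 at an unadjusted p under 0.05). Both designs have too few splits for a share under 0.05. Of 100 splits of the 12 arrays into 6 and 6, fitted as 2 groups, 1, the real one, called as many as 20585. The highest other called 14713. This argues against a chance split of these arrays for renal against bone marrow. It does not tell tissue from slide, which go together there, and replicates may be technical.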
